A study of Homo sapiens with 12 samples.

How the data were processed

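The data were ribosome profiling libraries, in which RNA fragments protected by ribosomes from RNase digestion are sequenced. Monosome libraries hold fragments covered by single ribosomes, and disome libraries hold the longer fragments covered by a pair of stacked ribosomes, as form when a ribosome runs into a slower one ahead of it. The 12 libraries made 6 groups of 2: monosomes and disomes from cells labelled as treated with DMSO (the solvent), with anisomycin at 0.01 µg/ml or with cycloheximide (CHX), both of which bind the ribosome and block elongation. The labels give 1 µM CHX for replicate 1 and 2 µM for replicate 2 of both kinds of library; the titles name both CHX alike, so they were kept as a single group whose spread includes the dose. The cells are labelled "HEK294T flip in" and wild type, a spelling close to that of HEK293T, the established human embryonic kidney line. The labels' treatment protocol, written for DMSO and another compound, states 2 h; no time is stated for the drugs used here. No label says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

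The deposited files hold whole-number read counts per transcript ID, not normalised, with 182398 rows in each library. Per the submitters' processing notes, CASAVA 1.8 and STAR 2.7.0a were used with the hg38 build; their roles, the counting tool and its settings are not given in the sources used here. Each row has a UCSC-style transcript ID, a length and a count. The length is missing on 88482 rows, whose counts sum to 0 in the 12 libraries, so the counted rows read as coding sequences. Their unit is not stated in the files. Only 33.1% of the lengths are multiples of 3, which a coding length in nucleotides would be, so lengths are given here in codons. The files do not pair the IDs with gene names, and only 2 IDs had a match in the reference table of 59792 genes, both without a count. Therefore no gene is named. The 21 gene lists, the polyproline comparison and the scaling to mitochondrially encoded genes that had been fixed before the data were examined could not be run, and 4 IDs are printed: 2 that rose and 2 that fell. Whether a row shares reads with a paralogue, a pseudogene or an overlapping gene could not be tested without names or positions.

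Isoforms of a gene share reads in these files, so the same read can stand on several rows. Rows with at least 100 counts over all libraries (44031 rows) were joined when they lay within 15 rows of each other and had the same profile over the libraries, meaning a chi-square under 5 or, for rows of at least 5000 counts, a root mean square deviation of log ratios over the monosome libraries under 0.05; identical rows were joined anywhere. This gave 14962 transcript groups, of which 7127 held a single row and the largest 60 rows, and the row with the highest count stood for its group. Of neighbouring rows 46.9% were joined directly, against 1.30% of pairs 5000 rows apart. Tested on simulated isoforms of 3000 profiles, the procedure joined 100.0% of true neighbours and 6.17% of neighbours from different profiles. The simulated isoforms kept most reads of a shared profile and came from rows with more counts than the 100 required here. Joining them was thus nearly built in, and the 100.0% does not carry over to the real rows. The rule replaces the planned sum per gene symbol. Isoforms with distinct profiles remained separate groups, and so did some rows with near-equal counts. The row of uc058iot.1, followed below, had 26981 counts in DMSO monosome replicate 1, and a row of the same length tested apart had 27404. Groups are thus not always separate genes, and call counts can include a gene more than once.

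Depth per library was counted over one row per group. It ran from 34748 to 267330 counts in disome libraries and from 548310 to 10392483 in monosome libraries. A count of 0 allows a level of up to 86.3 CPM (the usual scaling of counts by library total) in the shallowest disome library and 0.289 in the deepest monosome library, taking 3 counts as the limit. Intervals and limits cover counting error only, since no molecular identifiers are recorded.

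Counts were tested with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, TMM scaling, the package's filter on low counts by group, 1 mean per group) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 6 monosome libraries were fitted together (14958 groups tested, 3 residual degrees of freedom), as were the 6 disome libraries (2545 groups tested). A fit of all 12 libraries (9627 groups tested, 6 residual degrees of freedom) gave the contrast of disomes with monosomes and its change with treatment as an interaction term. The estimated biological coefficient of variation was 10.1% for monosomes and 12.4% for disomes. The SE of a log2 change was derived from the change and its test statistic, not fitted separately. "Rose" and "fell" refer to groups past the threshold. Scaling sets the bulk of each library equal, so the values are shares of a library, and absolute amounts of ribosomes or disomes cannot be read from them. Exact tests of a single value between 2 and 2 libraries cannot give a two-sided p below 0.333, so exponents and shares are given with their spread and no p.

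Counts were simulated from the fitted means and dispersions, with 100 groups changed by each fold. The changed groups were drawn only from the better-covered ones, so recovery in groups with the fewest counts was not measured. The monosome test of anisomycin recovered 84% of 2-fold and 97% of 4-fold changes, with 14958 groups simulated. The disome test of CHX recovered 36% and 89%, with 2545 groups simulated. The test of a disome-to-monosome change under CHX recovered 9% and 36%, with 9627 groups simulated, so most 2-fold changes of that ratio would be missed at this depth.

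Disome counts were also fitted per library with a quasi-Poisson model as a power of the monosome level (mean CPM of the same treatment, at least 10 CPM) times a power of coding length (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). On simulated counts the largest error of an exponent was 0.00934. Groups with a mean monosome level of at least 10 CPM were divided into 5 classes of coding length, and the share of disome counts in a class was set against its share of monosome counts. Rank correlations used scipy 1.17.1. This power fit and the other length and likeness measures, except the rank correlation of the DMSO ratio with length, were added after seeing the data. That correlation was planned with the longest coding sequence of each gene. Here the length of a group is that of the row standing for it, so a group of a shorter isoform counts as short.

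Replicates were separate libraries by their counts. The chi-square per degree of freedom between the 2 libraries of a group was 2.62 to 3.36 for monosomes and 1.57 to 1.90 for disomes. Disome and monosome libraries of a treatment share numbers in the labels. Their deviations between replicate 1 and replicate 2 correlated at 0.290 for anisomycin, 0.129 for CHX and 0.397 for DMSO over 172 groups. Between disomes and monosomes of unlike treatments the values ran from -0.193 to 0.0598. Numbers were taken to pair the 2 kinds of library within a treatment. For CHX this is weak, since -0.193 is larger in size than 0.129 and libraries of a number also share a labelled dose. This pairing rests on the counts, as no label states it.

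The printed IDs came from the rule fixed before the data were examined: groups past the threshold, with a mean of at least 10 CPM and no overlap between the compared libraries, ordered by fold change. The first rise and the first fall of each drug against DMSO in the monosome libraries are printed and followed through the other comparisons. The alternatives were DESeq2-type size factors in place of TMM, no filter or a filter at a mean of 10 CPM, DESeq2 1.42.0, a replicate block, fits of the 4 compared libraries alone and leaving out each library. Every distinct row in place of 1 per group, a block with crossed numbers and each drug against another DMSO library were added after seeing the data.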

Results

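The series compared ribosome footprints of human cells under low doses of 2 elongation inhibitors with those under solvent, as control experiments in a study of the compound girolline and the translation factor eIF5A. Monosome and disome footprints were each sequenced from 2 DMSO, 2 anisomycin and 2 CHX libraries. Counted once per transcript group, the monosome libraries held 10392483 and 4173616 counts (DMSO), 548310 and 6762630 (anisomycin) and 5583869 and 2073396 (CHX). The disome libraries held 101123 and 49364 counts (DMSO), 34748 and 105827 (anisomycin) and 165865 and 267330 (CHX). The first anisomycin library was thus the shallowest of both kinds. The 100 groups with the most counts took 21% to 22.8% of each monosome library. They took 19.4% and 19.5% of the anisomycin disome libraries, 23.9% and 23.5% of the DMSO ones and 25.5% and 25.9% of the CHX ones.

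The first question was which transcripts carried stacked ribosomes without a drug. In DMSO, disome footprints lay on longer coding sequences than monosome footprints did. Groups with 6 to 130 codons held 0.765 times the share of disome counts that they held of monosome counts, with a log2 ratio of -0.39 ± 0.01 (SD, n = 2). Those with 674 to 7593 codons held 1.68 times their monosome share, with a log2 ratio of 0.75 ± 0.02 (SD, n = 2), and the 3 classes between lay in order. Across 9627 groups, which are not independent replicates, the fitted ratio correlated with coding length at a Spearman rho of 0.401, and at 0.388 and 0.304 in the library pairs numbered 1 and 2. In edgeR's quasi-likelihood test, 1098 groups were higher in disomes and 1623 lower, with median lengths of 595.5 and 177 codons against 328 for the others. Which side held more calls depended on the test, as DESeq2 called 1381 groups higher in disomes and 1042 lower. Without DMSO disome replicate 1 or 2 the 2721 calls became 1022 and 1781.

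**Figure D1:**
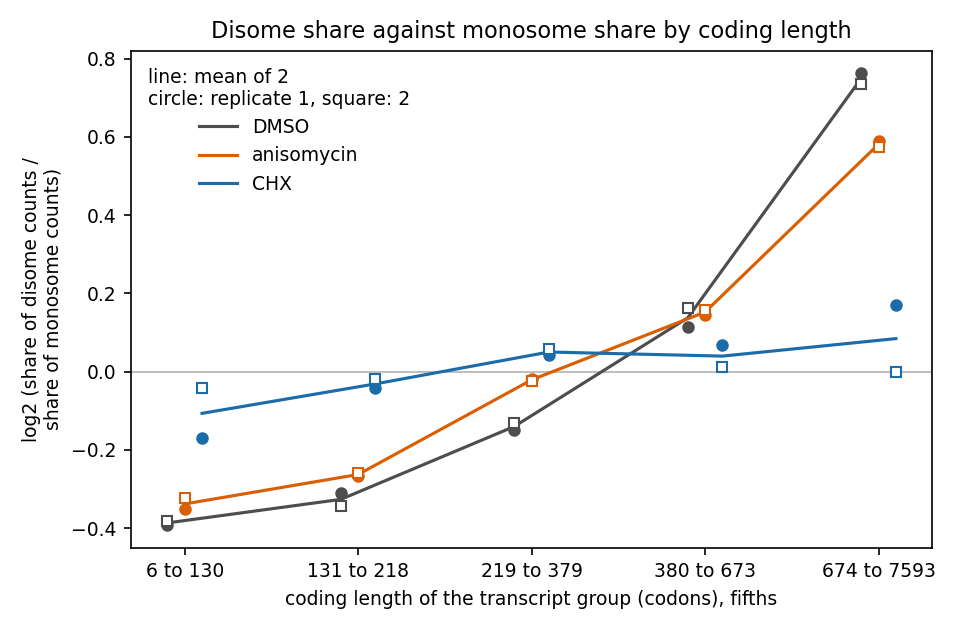
Log2 ratio of the share of disome counts to the share of monosome counts (y axis) in 5 classes of coding length in codons (x axis) under DMSO, anisomycin and CHX; lines join means of 2 library pairs, circles are replicate 1 and open squares replicate 2. The mean ratio climbed from -0.39 to 0.75 in DMSO and from -0.34 to 0.58 under anisomycin. Under CHX it was -0.11 in the shortest class and 0.08 in the longest, without a steady climb between. In the longest class CHX replicate 1 had 0.17 and replicate 2 -0.0014.

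The comparison of anisomycin with DMSO in monosomes asked how the share of footprints per transcript changed under the drug. No library here measured RNA levels. A change in the amount of a transcript and a change in ribosomes per transcript thus cannot be told apart, for either drug. Anisomycin changed 4145 of 14958 groups, with 2194 rises and 1951 falls, and the rises were the larger changes: 1020 reached 2-fold against 518 of the falls. Short coding sequences rose most often. Of the groups in the shortest length class 26.3% rose and 13.4% fell, against 7.77% and 10.1% in the longest class. Across all groups with at least 10 CPM there was little trend: the change correlated with coding length at a mean Spearman rho of -0.0514 (-0.0247 and -0.0781 for replicates 1 and 2), less than the -0.0923 between the DMSO libraries. The largest rise was in uc060rlc.1, with a listed length of 61 codons, from 6.53 ± 1.10 to 186 ± 1.91 CPM (SD, n = 2). Its log2 change was 4.66 ± 0.19 (SE, adjusted p = 4.56e-22, edgeR). The row with the adjoining ID, of 177 codons and tested apart, rose by 4.15 on the log2 scale. Whether both belong to a single gene could not be told without names. The largest fall was in uc062oid.1, with 320 codons, from 38.5 ± 4.32 to 13.2 ± 7.15 CPM (SD, n = 2), a log2 change of -2.20 ± 0.24 (SE; adjusted p = 8.99e-09, edgeR). For uc062oid.1, replicates 1 and 2 of anisomycin had 18.2 and 8.13 CPM, from 10 and 55 counts. The fit gives more weight to the larger count, so its log2 change is larger in size than that of the mean levels. Across groups, too, the anisomycin libraries differed in the size of the change. Over 1782 well-covered groups, the log2 changes against DMSO had an SD of 0.39 in replicate 1 and 0.57 in replicate 2, with a correlation of 0.833. Leaving out replicate 2 of anisomycin left 294 calls, and the fall of uc062oid.1 was then -1.17 with an edgeR adjusted p of 0.159; without DMSO replicate 1 or 2 there were 1797 and 2111 calls. DESeq2 called 1163 groups, with 522 rises and 641 falls.

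CHX changed fewer monosome groups, and mostly upwards: 500 rose and 115 fell out of 14958, of which 179 and 44 reached 2-fold. Rises were most frequent in groups of 380 to 673 codons, at 5.37%, against 2.17% in the shortest class. The change in level correlated with coding length at a mean Spearman rho of 0.243 over 10554 groups, 0.182 for replicate 1 and 0.305 for replicate 2, where the DMSO libraries differed from each other with a rho of -0.0923. Over the 3582 groups with at least 50 CPM the mean was 0.156, with 0.0547 for replicate 1 and 0.257 for replicate 2, against -0.0563 between the DMSO libraries. The largest rise was in uc003puk.3 (335 codons), from 7.35 ± 0.455 to 59.1 ± 10.6 CPM (SD, n = 2), a log2 change of 3.03 ± 0.21 (SE; adjusted p = 1.94e-14, edgeR). The largest fall was in uc058iot.1 (647 codons), from 2643 ± 66.3 to 407 ± 55.6 CPM (SD, n = 2), a log2 change of -2.67 ± 0.15 (SE; adjusted p = 5.84e-17, edgeR). The groups of uc058iot.1 and uc003puk.3 were each joined from 5 rows by their like profiles, and that of uc062oid.1 from 2. The levels given are those of the row with the highest count. Which row of a group the reads came from cannot be told. The count of 615 fell to 231 and 245 without CHX replicate 1 or 2, and to 59 and 202 without DMSO replicate 1 or 2. DESeq2 gave 143 calls, and a fit of only the 4 compared libraries gave 1058.

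Set directly against each other in monosomes, anisomycin was higher than CHX in 1672 groups and lower in 1541. The higher ones were short, with a median of 120 codons, against 234 codons for the lower ones and 312 for the rest. All 4 followed transcripts differed between the drugs. uc060rlc.1 was higher under anisomycin by 3.72 ± 0.19 and uc058iot.1 by 1.64 ± 0.14 on the log2 scale (SE; adjusted p = 4.02e-18 and 6.11e-11, edgeR). uc062oid.1 and uc003puk.3 were lower, with log2 differences of -1.78 ± 0.26 and -1.20 ± 0.20 (SE; adjusted p = 2.72e-06 and 2.32e-05, edgeR). Without anisomycin replicate 2 there were 367 calls and uc062oid.1 was not among them, its log2 difference having shrunk to -0.75 (edgeR adjusted p = 0.485); without CHX replicate 1 or 2 there were 1709 and 2095. The balance turned slightly without anisomycin replicate 1 or 2, to 2021 higher and 2147 lower, and 182 and 185. DESeq2 gave 885.

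The responses to the 2 drugs overlapped in both kinds of library. In monosomes 261 groups rose under both drugs, where independent lists would share 73.3, 38 fell under both, where they would share 15, and 50 moved in opposite directions. uc003puk.3 rose under anisomycin too, by 1.83 ± 0.23 on the log2 scale (SE; adjusted p = 1.15e-07, edgeR), and without anisomycin replicate 2 the change was of similar size, 1.63, but no longer passed (adjusted p = 0.0745, edgeR). uc058iot.1 fell under anisomycin too, with a log2 change of -1.04 ± 0.14 (SE; adjusted p = 6.71e-07, edgeR). uc060rlc.1 rose under CHX by 0.95 ± 0.24 (SE; adjusted p = 0.0154, edgeR), a call that ended without any 1 of the 4 libraries compared (log2 changes from 0.85 to 1.15, adjusted p from 0.0501 to 0.276, edgeR) and with DESeq2 (0.93, adjusted p = 0.0966). The log2 changes correlated across groups at r = 0.347 with a covariance of 0.0916. Unchanged groups simulated against the same DMSO libraries gave r = 0.389 and a covariance of 0.0289. In disomes 82 groups rose and 48 fell under both drugs, where independent lists would share 30.9 and 20.4, and 42 moved oppositely. The covariance was 0.533 (r = 0.527), against 0.172 (r = 0.576) simulated. The overlap was also seen when the drugs shared no control library. With anisomycin against DMSO replicate 1 and CHX against replicate 2, 38 monosome groups rose and 7 fell under both, where independent lists would share 3.56 and 1.03. The opposite assignment gave 64 and 8, where they would share 10.1 and 2.11. In disomes 25 rose and 22 fell under both (12.5 and 7.73 if independent) with 34 opposite, and 31 and 12 (12.3 and 8.07) with 31 opposite. The covariances were 0.084 and 0.0516 in monosomes and 0.482 and 0.448 in disomes, where simulated unchanged groups gave at most 0.00165 and 0.0345.

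In disomes, anisomycin raised 258 and lowered 208 of 2545 groups, with a median change of 1.97 for rises and -1.47 for falls on the log2 scale. Groups at the short end changed most often in both directions: 21.8% of those tested in the shortest class rose and 15.2% fell, against 2.92% and 4.76% in the longest. uc060rlc.1 had 7 and 15 disome counts under anisomycin and 0 in both DMSO libraries (edgeR adjusted p = 9.92e-05, DESeq2 gave no adjusted p). Its level over the pooled anisomycin libraries was 7.85 times the limit of 3 counts over the DMSO group. That ratio leaves out the counting error of the anisomycin counts. uc058iot.1 fell from 3964 ± 124 to 1688 ± 583 CPM (SD, n = 2), a log2 change of -1.26 ± 0.20 (SE; adjusted p = 1.09e-06, edgeR). The other 2 followed transcripts had too few disome counts to be tested. Without anisomycin replicate 2 the 466 calls became 133, and without DMSO replicate 1 they became 250. With no filter on low counts there were 231, and DESeq2 gave 147.

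CHX sorted disome changes by coding length. Of 2545 groups, 305 rose, with a median length of 161 codons, and 249 fell, with a median of 960 codons; the groups not called had a median of 358. In the shortest class 96 groups rose and 12 fell out of 409. In the longest class 1 rose and 170 fell out of 651, and the log2 changes correlated with length at a Spearman rho of -0.524 across groups. uc058iot.1, with 647 codons, fell from 3964 ± 124 to 423 ± 36 CPM (SD, n = 2), a log2 change of -3.14 ± 0.20 (SE; adjusted p = 6.19e-20, edgeR). uc060rlc.1 had 1 and 2 disome counts under CHX and 0 in DMSO and did not pass (adjusted p = 0.364, edgeR). Calls numbered 364 and 215 without CHX replicate 1 or 2, and 230 and 340 without DMSO replicate 1 or 2, against 554. The falls depended on the test: with no filter on low counts 266 groups rose and 34 fell, and DESeq2 called 131 rises and 42 falls.

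**Figure D2:**
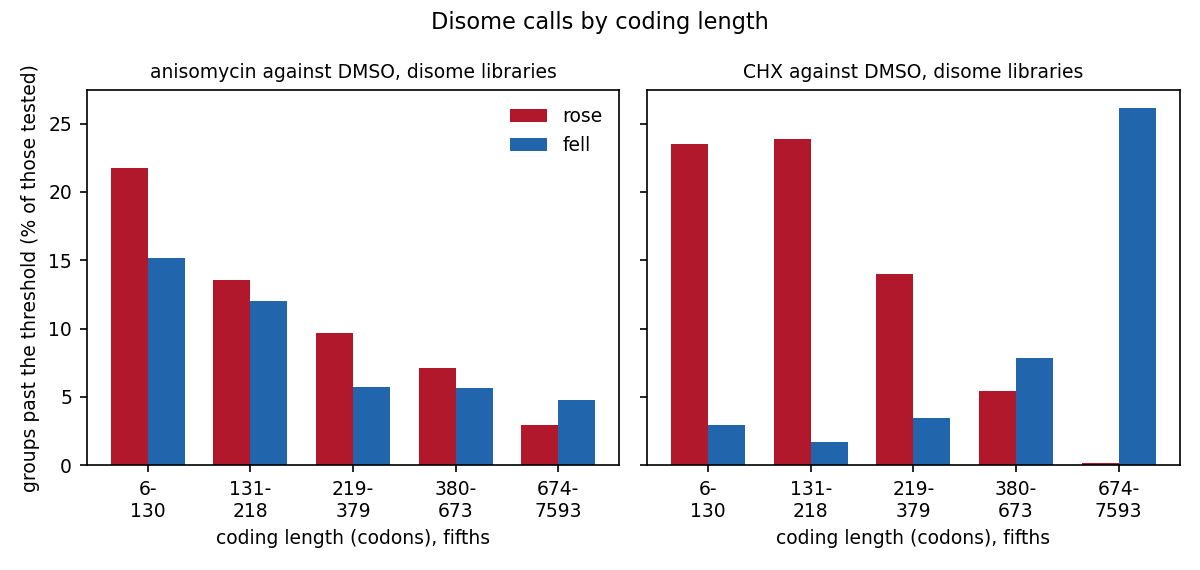
Percentage of tested transcript groups that rose (red) or fell (blue) in disome libraries against DMSO (y axis) in 5 classes of coding length in codons (x axis), for anisomycin (left) and CHX (right). Under CHX 23.5% of the shortest class rose and 26.1% of the longest class fell; under anisomycin 21.8% of the shortest class rose and 4.76% of the longest class fell.

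Between the drugs, 293 disome groups were higher under anisomycin than under CHX and 299 lower. Those higher under anisomycin had a median length of 316 codons and those lower 155 codons, where the groups not called had 412. uc060rlc.1 was higher under anisomycin with 7 and 15 counts against 1 and 2, a log2 difference of 4.33 ± 0.74 (SE; adjusted p = 5.12e-06, edgeR). uc058iot.1 was higher by 1.87 ± 0.21 (SE; adjusted p = 2.31e-10, edgeR). The 592 calls became 269 without anisomycin replicate 2 and 345 without CHX replicate 2. DESeq2 gave 248, of which 73 were higher and 175 lower, and with no filter on low counts 92 were higher and 420 lower.

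Whether disomes changed beyond the monosomes of the same transcripts was tested as an interaction in the fit of all 12 libraries, which does not use the pairing of disome and monosome libraries by number. With a block for the library number within each treatment the counts were 172 for anisomycin, 225 for CHX and 314 between the drugs, against 215, 334 and 379. Under CHX the disome-to-monosome ratio rose in 276 groups, with a median length of 173 codons, and fell in 58, with a median of 804.5 codons. Under anisomycin it rose in 121 groups and fell in 94, with medians of 146 and 169 codons. That balance was not stable: it was 59 rises and 110 falls without DMSO disome replicate 2, 23 and 39 without anisomycin disome replicate 2, and 160 and 63 without anisomycin disome replicate 1. The 8 largest rises of the ratio under each drug, by the rule for printed IDs, had 0 disome counts in both DMSO libraries. Their log2 changes, 9.97 to 10.5 for CHX and 10.6 to 11.4 for anisomycin, thus have no measured base. The median rise was 1.49 under CHX and 2.79 under anisomycin. Between the drugs 69 groups had a higher ratio under anisomycin and 310 a lower one. None of the 4 followed transcripts passed any of these 3 tests (edgeR adjusted p from 0.356 to 0.946), so the disome fall of uc058iot.1 was not distinguishable from its monosome fall at this depth. With DESeq2-type size factors the CHX calls split into 193 rises and 85 falls. That scaling moved the median log2 ratio change of all groups under CHX from 0.20 to 0.06, and the direction of small ratio changes is relative to that centre. Leaving out single libraries moved the CHX count from 334 to between 151 (without CHX disome replicate 2) and 474 (without CHX disome replicate 1), with 201 and 153 without DMSO disome replicate 1 or 2, and 207 and 180 without monosome replicate 2 of CHX or DMSO. The anisomycin count of 215 became 62 without anisomycin disome replicate 2 and 76 without DMSO disome replicate 1, and the count of 379 between the drugs became 240 and 195 without disome replicate 2 of anisomycin or CHX.

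The dependence of disomes on length and on monosome level was then measured per library, as the exponents of a fit to disome counts. An exponent of 0 for length means that the disome count at a given monosome level did not change with coding length. In DMSO the length exponent was 0.311 ± 0.00403 (SD, n = 2). It was 0.224 ± 0.0186 (SD, n = 2) under anisomycin, and 0.0558 ± 0.0170 (SD, n = 2) under CHX. The libraries at 1 µM and 2 µM CHX had exponents of 0.0678 and 0.0437, each with an SE of 0.0075. With the monosome library of the same number as the only reference they lay further apart, at 0.0954 and 0.0167. The exponent of monosome level was 0.949 ± 0.00263 in DMSO, 0.905 ± 0.000922 under anisomycin and 1.02 ± 0.0038 under CHX (SD, n = 2). For both exponents the differences from DMSO exceeded the spread between libraries, but their size depended on the groups and reference used. With at least 50 monosome CPM the difference in the exponent of monosome level was 0.0239 in place of 0.0725 for CHX and -0.0801 in place of -0.0437 for anisomycin, and the anisomycin difference in the length exponent was -0.0521 in place of -0.0869. With all 6 monosome libraries as the reference the 2 anisomycin differences were -0.0843 and -0.136. Disome libraries under CHX also resembled the monosome libraries of the same number more closely. With all libraries thinned to 34748 counts, the correlation across groups was 0.708 ± 0.000481 for CHX, against 0.621 ± 0.00505 for DMSO and 0.62 ± 0.0137 for anisomycin (SD, n = 2). The DMSO monosome libraries thinned in the same way correlated with each other at 0.769.

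**Figure D3:**
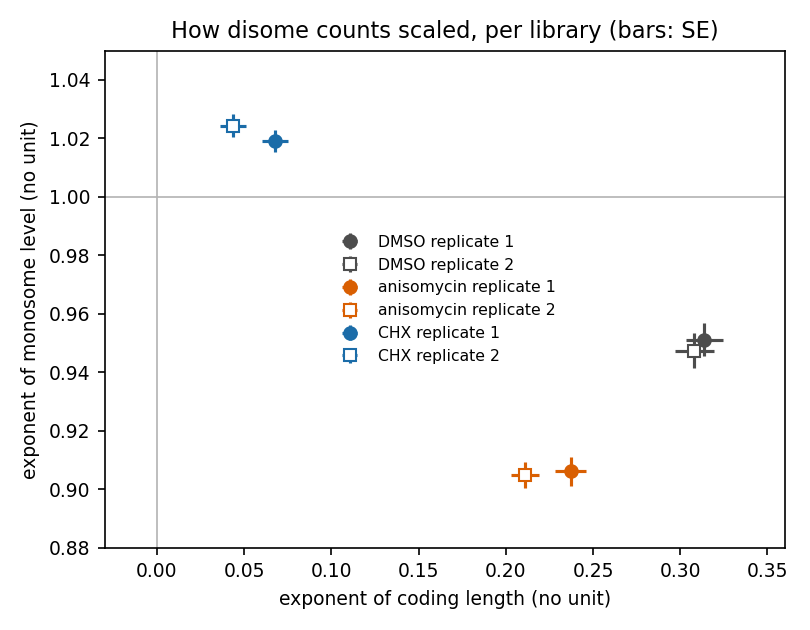
Exponent of monosome level (y axis, no unit) against exponent of coding length (x axis, no unit) for each of the 6 disome libraries; circles are replicate 1, open squares replicate 2 and bars the standard error of the fit. The CHX libraries sit at length exponents of 0.0678 and 0.0437 and the DMSO libraries at 0.314 and 0.308, with anisomycin between them at 0.237 and 0.211.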

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

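Among the tests in this part, the change of the length exponent with depth, the range of the CHX exponents and the mixtures of measured profiles were chosen after the exponents had been seen; the count of groups above both source profiles was set beforehand.

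The treatment effect differed between disome and monosome libraries, by an interaction term in edgeR, in 334 groups for CHX against DMSO, in 215 for anisomycin against DMSO and in 379 between the drugs. These 3 counts stand here because the same treatment contrast was tested for a difference between the 2 kinds of library.

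The length exponent of disome libraries was lower under CHX than in DMSO. The difference from DMSO was -0.255, and the greater depth of the CHX libraries is argued against as its whole cause: the exponent changed by only 0.0057 and -0.0262 between the shallower and the deeper library of DMSO and of anisomycin (2.05 and 3.05 times the depth), and the steeper of these predicts -0.0257 at the 2.98 times greater depth of CHX. Carry-over of monosome fragments as the only difference from DMSO disomes is also argued against. Of the groups tested, 99 lay above both the DMSO disome and the CHX monosome level, where 20 simulated mixtures gave at most 2. These mixtures had the fitted 54.7% monosome profile, and other weights were not simulated. All mixtures here kept the DMSO disome profile unchanged, whereas CHX changed 615 groups in monosomes. Carry-over joined to such changes in level is thus not argued against. A 55% mixture would have an exponent of 0.156, above both CHX libraries. A mixture with 85% monosome profile, which brings the exponent down to 0.0527, would leave disome-rich groups at 1.73 times their monosome share, where CHX libraries had 3.51 and 3.37. The mixture nearest to these ratios, with 50% and a ratio of 3.425, would have an exponent of 0.173. A partial carry-over and disomes formed broadly over translated messages under CHX cannot be told apart, since the highest CHX exponent of 0.0678 lies below both DMSO libraries under either, and these counts hold no footprint lengths.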

How the results depend on the processing

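No call of the followed transcripts reversed, nor did any length, likeness or covariance measure larger than its spread. The direction of the other called groups was not compared between fits. The side with more calls, rises or falls, turned in 7 fits, of which the report gives 6. The other was every distinct row for disomes of anisomycin against CHX, with 664 higher and 631 lower. Of 56 other settings fixed before the data were examined for the 10 call counts, not counting left-out libraries, 47 stayed within 1.5 times the reported count. DESeq2 gave 1163, 143 and 885 calls in the monosome comparisons (anisomycin and CHX against DMSO, then anisomycin against CHX) and 147, 173 and 248 in the disome ones. Fitting only the 4 compared libraries gave 1058 for CHX monosomes. With no filter on low counts there were 231 and 300 disome calls for anisomycin and CHX; the cause was not tested. Every distinct row in place of 1 row per group, chosen after seeing the data, counts isoforms repeatedly and tests more rows: it gave 9754, 1613 and 6960 monosome calls, 1085, 1280 and 1295 disome calls, 6151 for disomes against monosomes, and 588, 1064 and 923 ratio changes (anisomycin, CHX, between drugs). The filter at a mean of 10 CPM removed no disome group and tests nothing there. With no filter on low counts 14962 monosome groups were tested in place of 14958, which tests little. The 47 settings include these, whose agreement was nearly fixed in advance.

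Replicate numbers did not pair treatments: deviations correlated between -0.127 and 0.00595 for monosomes and between -0.243 and -0.0629 for disomes. With the replicate block (by number over treatments, or within each treatment where both kinds of library were fitted) the counts were 3221, 506 and 2546 for monosomes, 413, 509 and 581 for disomes, 2464 for disomes against monosomes and 172, 225 and 314 for the ratio changes; it moved none by over 1.5 times and ended no call of the followed transcripts. With crossed numbers the block gave 3867 for anisomycin monosomes, and 554 and 557 for CHX disomes against DMSO and between the drugs.

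Leaving out each library in turn, where a lone library is assumed to vary like the others, gave 294 to 5196 calls for anisomycin monosomes, 59 to 245 for CHX monosomes and 367 to 4168 between the drugs. Disome calls ranged over 133 to 397, 215 to 364 and 269 to 513, disomes against monosomes over 1022 to 2458, and ratio changes over 62 to 274, 151 to 474 and 195 to 454. The difference in length exponent from DMSO ranged over -0.10 to -0.0738 for anisomycin and -0.267 to -0.243 for CHX, and in abundance exponent over -0.0456 to -0.0419 and 0.0698 to 0.0752. The rank correlation of the DMSO ratio with length was 0.304 to 0.388, that of monosome changes with length -0.0781 to -0.0247 (anisomycin) and 0.182 to 0.305 (CHX), and likeness differed from DMSO by -0.0108 to 0.0086 and 0.0835 to 0.0906.

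Other settings for the length measures were chosen after seeing the data, and the causes of their shifts were not tested. The reported length exponent differences were -0.0869 (anisomycin) and -0.255 (CHX). With all 6 monosome libraries as the reference they were -0.136 and -0.289, and with at least 50 monosome CPM the former was -0.0521. The abundance exponent difference, reported as -0.0437 for anisomycin, was -0.0801 (50 CPM), -0.0843 (all monosomes) and -0.0623 (every distinct row). For CHX, reported as 0.0725, it was 0.0239 (50 CPM) and 0.0602 (every distinct row). The correlation of CHX monosome changes with length was 0.156 at 50 CPM. Likeness under anisomycin differed by -0.0144 at 100 CPM. At a mean of 10 CPM the excess covariance of the monosome responses was 0.0595, against 0.0627. With anisomycin against DMSO replicate 1 and CHX against replicate 2, or the opposite, it was 0.0843 and 0.0519, and in disomes 0.469 and 0.443, against 0.361.

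For the followed transcripts, 172 of 181 alternatives kept the 16 calls, 9 ended one, and 1 of 230 added one among 18 values not called. Scaling to mitochondrially encoded genes, gene lists and polyproline runs were not run for lack of names and sequences, and a pseudocount does not apply to counts.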

Other observations

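Of the tests in this part, the share of change in rises and falls was set before its result was seen; the monosome and disome SD ratios, the value expected under a uniform weakening and the choice of disome-rich groups in drug libraries were chosen afterwards.

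The transcript groups richest in disomes without a drug had a lower ratio of disome share to monosome share under both drugs. The tenth of groups with the highest disome-to-monosome ratio was chosen in DMSO replicate 1 (207 groups, median length 659 codons) and measured in the other libraries. Their disome share was 6.77 times their monosome share in DMSO replicate 2, 3.67 and 3.28 times under anisomycin and 3.51 and 3.37 times under CHX. Chosen instead in DMSO replicate 2 (94 groups), the values were 6.09 in DMSO replicate 1, 3.44 and 3.16 under anisomycin and 3.36 and 3.28 under CHX. Groups chosen as highest in DMSO can be lower elsewhere by the choice alone, so the same choice was made in the drug libraries. Groups chosen in CHX replicate 1 or 2 had 2.88 and 2.50 in the other CHX library, and 3.56 and 3.63, or 2.94 and 2.97, in DMSO, so for CHX the ratio was higher in DMSO under either choice. Groups chosen in anisomycin replicate 1 or 2 had 3.31 and 3.60 in the other anisomycin library, and 2.59 and 2.73, or 3.52 and 3.66, in DMSO, so for anisomycin the difference depended on where the groups were chosen. These are ratios of library shares and do not give amounts of disomes. No cause was tested.

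Groups with a listed length under 20 codons, 33 in all, took a larger share of the counts in both kinds of library under anisomycin. The counts do not show whether pairs of stacked ribosomes lay within coding sequences this short. Reads from overlapping or longer sequences could not be told apart from them. In disomes the share was 0.107% (0.075% to 0.147%, exact 95% interval) and 0.145% (0.123% to 0.169%) under anisomycin, 0.0277% (0.0184% to 0.04%) and 0.0121% (0.00446% to 0.0264%) in DMSO, and 0.0301% and 0.0168% under CHX. In monosomes it was 0.16% and 0.21% under anisomycin, against 0.0919% and 0.0835% in DMSO. The largest group of each library held 46.0% and 42.5% of these disome counts under anisomycin. In anisomycin monosomes it held 42.2% and 49.9%, against 36.2% and 34.0% in DMSO monosomes. It was not the same group in both kinds. The largest in disomes, with a listed length of 13 codons, had 17 and 65 disome counts under anisomycin, but 14 of 879 and 278 of 14207 monosome counts. In the 246 groups under 40 codons the disome share differed less between anisomycin and DMSO. They held 0.754% and 0.807% of disome counts under anisomycin, 0.651% and 0.606% in DMSO and 0.724% and 0.72% under CHX. The intervals cover counting error only.

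Disome counts per 100 monosome counts were 0.973 and 1.18 in DMSO, 6.34 and 1.56 under anisomycin and 2.97 and 12.9 under CHX. These ratios depend on how deeply each library was sequenced and do not measure the amount of disomes.

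Anisomycin replicate 1 showed smaller changes than replicate 2, with a slope of 0.575 across 1782 monosome groups, and lower depth does not account for this: counting noise widens changes, as in replicate 2 thinned to that depth (SD 1.03 times as large), while the SD in replicate 1 was 0.691 times that of replicate 2 (bootstrap 95% interval 0.663 to 0.719). Reads of DMSO libraries mixed into replicate 1, or cells there that did not respond, would give rises and falls the same fraction of the change seen in replicate 2, and a uniformly weaker response on the log scale would give falls a fraction higher by 0.214. The fractions were 0.512 for 103 rises and 0.585 for 145 falls, a difference of 0.0731 (bootstrap 95% interval 0.0256 to 0.130), which lies between them. The difference meets the bound of 0.1 set for mixing beforehand, but its interval does not, and that the interval should meet it was required only after the value was seen. The disome changes of replicate 1 had an SD of 0.822 times that of replicate 2, so a weaker response of these cells may be part of it; mixing and a weaker response cannot be told apart here.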
